A study of Mus musculus with 2 samples.

How the data were processed

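The samples were 2 pools of total RNA, each from Panc02 tumours of 6 mice, 1 pool per housing condition. The pools were labelled with Cy3 and hybridised to 1 Agilent whole mouse genome array each, per the labels' protocols. The files' headers place both arrays on 1 slide, so slide and scan do not separate the groups. Because the RNA was pooled before labelling, the values hold no spread between mice.

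The deposited scanner files give a linear intensity per spot made with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. Per the file headers, the software removed a spatial background trend and wrote a processed intensity, a mean intensity and a local background, with marks for spots that are well above background, saturated, non-uniform or population outliers. Background steps of this kind change dim spots more than bright ones. A second deposited table, also used here, holds 1 log2 value per probe and array for 30319 probes. The authors' processing of this log2 table beyond Feature Extraction is not given in the sources used here. Set against log2 of the processed intensity of the same array, its columns correlated across probes with r = 1.00 for both pools, so that scale and direction are those of the scanner values, while the scaling step and the centring are unstated. The column medians were 8.54 for the standard and 8.56 for the enriched environment pool, and the sorted columns differed by a median of 0.015. Of its probes, 30298 were those found here to be well above background on both arrays. The table was used as an alternative only.

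The main values were log2 of the processed intensity minus the 75th percentile of the same array, which was 753 in the standard and 984 in the enriched environment pool before the logarithm. The 1639 control spots were left out, as were spots marked as outliers, 66 in the standard and 70 in the enriched environment pool. Spots of 1 probe were averaged. A probe was used where it was well above background on both arrays, which held for 30298 of 41161 usable probes, and the probes of a gene were averaged. Of 41174 probes, 22951 received a current symbol through their unversioned RefSeq accession in a table of assembly GRCm38.p6, and 18223 kept the name in the file. Several probes were measured for 6608 genes, and 73.5% of these had all probes on 1 side of 0. Among the 737 of these genes that differed by at least 2-fold, the share was 97.6%. Where a gene was well above background on 1 array only, its brighter level was set against the higher of the lowest signal among probes well above background on the other array and the probe's own signal there, and the ratio is given as a bound. This held for 991 genes on the standard and 940 on the enriched environment array. The brighter level lay above that reference in 991 and 611 of them, and 561 and 123 had bounds of at least 2-fold. The lowest signal well above background was -5.685 on the standard and -6.205 on the enriched environment array. Genes bright on the standard array only could therefore reach 2-fold more easily, and the 2 counts do not compare evenly. Probe positions are those of the array design on mm7.

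With 1 array per group no p-value was computed. Genes were counted by a difference of at least 2-fold. The 46 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 15 highest and 15 lowest differences among genes with a plain symbol, all probes in 1 direction and a mean level in the upper 75% of measured genes, then 5 genes per direction with the largest bounds, then in each list the 3 members with the largest difference and up to 6 that were at least 2-fold apart, with other members of lists outside their random range named as needed. A few genes that the rule selects are not reported here. A list with at least 5 measured genes was described by the percentile of its median among the medians of 10000 random lists of the same size, drawn from 20 bins of mean level, and was taken to stand apart outside the central 95% of these medians. The percentile describes these 2 arrays and is no test of the housing. Lists of brown adipocyte and bone genes, of glycolytic isoforms and of differentiated epidermis, mitochondrial isoform and granule genes were added later and are described by their medians.

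The steps were tested on simulated data made from the standard environment array over 20852 genes. The noise per gene had an SD of 0.57, a robust estimate of spread (from the median absolute deviation) of the observed differences between the 2 pools. Known log2 changes of 2 and -2 passed the 2-fold threshold in 94.0% of genes each, and changes of 1 and -1, which lie on the threshold, in 42.0% and 58.0%. Of unchanged genes, 8.10% passed it in either direction, and 5 of 100 unchanged lists of 25 genes stood apart. Because the noise was taken from the differences between the pools, which hold real differences too, the 8.10% is no technical error rate. The simulated genes varied independently, so the lists stand for no list whose genes vary together.

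The alternatives were quantile normalization, scaling by the median, an intensity-dependent loess, normexp background correction with an offset of 50, no background correction, 3 other filters on dim probes, outlier spots kept, the brightest probe of each gene, the authors' log2 table, thresholds of 1.5-fold and 3-fold, and random lists that were not matched on level. A list median was taken as moved where it left the 95% interval of 2000 bootstrap draws of the list's genes. The work used R 4.3.3 with limma 3.58.1 for normexp, quantile and loess, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.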

Results

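Transcript levels were measured in subcutaneous tumours grown from Panc02 cells, a mouse pancreatic carcinoma line, in C57BL/6 mice kept in 1 of 2 kinds of housing. The standard environment is ordinary laboratory caging, and an enriched environment is housing that offers animals more stimulation. Mice entered the housing at 3 weeks of age and stayed in it for 5 weeks after the tumour cells were injected. RNA from the tumours of 6 mice was pooled for each housing, and each pool was hybridised to 1 one-colour array, so that there were no replicates and no test between the housings could be made. Every value below therefore describes these 2 pools, and the number of arrays limits the precision. Of the 43379 spots that were not controls, 77.2% were well above background on the standard environment array and 77.4% on the enriched environment array, and none was saturated. A level is a log2 intensity relative to the 75th percentile of its array, and a difference is the enriched environment level minus the standard environment level.

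The comparison asked which transcripts differ between tumours from the enriched and the standard housing. The 2 pools differed most in the transcripts of skeletal muscle, which were lower in the enriched environment pool by a median log2 difference of -7.73, or 213-fold. Genes of mitochondrial respiration, the tricarboxylic acid cycle and fatty acid oxidation were lower by medians of -0.85 to -1.62, and erythroid genes were lower by -3.98. Carcinoma epithelium genes were higher in the enriched environment pool by a median of 1.85, fibroblast and matrix genes by 1.64, and both cell cycle lists by 0.56 and 0.77. Of 20852 genes measured on both arrays, 1190 were at least 2-fold higher and 1972 at least 2-fold lower in the enriched environment pool, and the median difference of all measured genes was 0.03. Differences of more than 4 on the log2 scale were mostly in one direction, with 211 genes lower and 10 genes higher by at least that much.

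**Figure D1:**
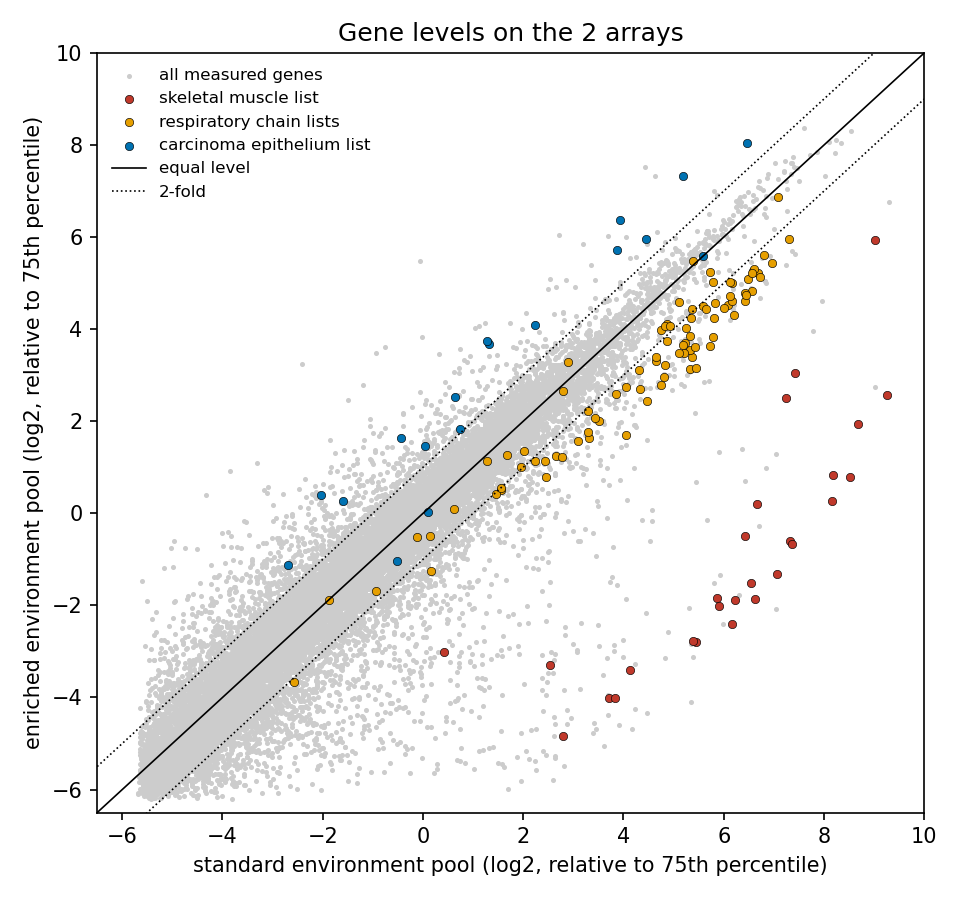
Level of each of 20852 measured genes in the standard environment pool (x axis) and the enriched environment pool (y axis), both as log2 intensity relative to the 75th percentile of the array, 1 array per pool. Coloured points are members of the skeletal muscle list (red), the respiratory chain lists (orange) and the carcinoma epithelium list (blue), the solid line marks equal levels and the dotted lines a 2-fold difference; all 27 muscle genes lie below the lower dotted line, with a median difference of -7.73.

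The genes that were furthest below their standard environment level in the enriched environment pool were those of the contractile and energy-storing apparatus of striated muscle, with a single gene of brown fat among them. Ckmt2, the mitochondrial creatine kinase of muscle, was at 7.03 in the standard environment pool and at -2.08 in the enriched environment pool, a difference of -9.11 or 554-fold. Ckm, the cytosolic muscle creatine kinase, differed by -8.56, Myh2, a fast myosin heavy chain, by -8.47 over 3 probes (SD between probes 0.09), and Mb, which encodes myoglobin, by -8.40. Hrc, Mybpc1, Actn2, Myot, Pygm, Myom2, Pvalb, Apobec2 and Myoz1 were also among the 15 lowest, with differences from -8.81 for Hrc to -8.16 for Myoz1. Ucp1, the uncoupling protein of brown adipocytes, differed by -8.86. In the muscle list, 27 of 27 measured members were at least 2-fold lower, and its median lay at percentile 0 of 10000 random lists matched on level. The list took 6.31% of the summed probe signal in the standard environment pool and 0.130% in the enriched environment pool. On the mm7 build, the Ckm probe lies on chromosome 7 from 17099247 to 17101854, the Mb probe on chromosome 15 from 77098591 to 77098650 and the Ucp1 probe on chromosome 8 from 81866808 to 81866867.

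Respiratory chain genes were lower in the enriched environment pool in each of the 4 lists, in the same pool in which the muscle list was lower by -7.73. All 37 measured subunits of complex I, which passes electrons from NADH to ubiquinone, were lower, 30 of them at least 2-fold, with a median of -1.41. Ndufs7 differed by -2.09, Ndufc1 by -1.97 and Ndufb2 by -1.97. Complexes II and III had a median of -1.59, with 13 of 14 genes at least 2-fold lower, among them Sdhb at -2.35 and Uqcrfs1 at -2.21. The ATP synthase list had a median of -1.35, with 15 of 17 genes at least 2-fold lower and Atp5g1 at -2.27. Cytochrome c oxidase had a median of -0.85, with 8 of 19 genes at least 2-fold lower, among them Cox7b at -1.55 and Cox5b at -1.52. The tricarboxylic acid cycle list was lower by a median of -1.62, with 15 of 19 genes at least 2-fold lower and all 3 measured subunits of NAD-dependent isocitrate dehydrogenase among the largest differences, Idh3b at -2.86, Idh3a at -2.28 and Idh3g at -1.72. Each of these lists lay at percentile 0 of its random lists. The mitochondrial lists were fixed with the knowledge that the study wrote about mitochondria-related genes in these tumours, so they are not independent evidence of a direction. None of their members is in the muscle list, where the oxidase subunits Cox6a2 and Cox7a1, typical of muscle, were placed. This follows from how the lists were written and does not separate these genes from the muscle signal.

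Fatty acid oxidation, glycolysis and mitochondrial maintenance genes also lay lower, beside the same difference of -7.73 in the muscle list and of -8.86 in Ucp1. In the beta-oxidation list 13 of 20 genes were at least 2-fold lower, with a median of -1.26. Its largest differences were in Cpt1b, the muscle-type carnitine palmitoyltransferase, at -4.97, in Ppara, a nuclear receptor that switches on fat oxidation, at -3.78, and in Decr1 at -3.09. Glycolysis had a median of -0.67 with 7 of 19 genes at least 2-fold lower. It was led by Pfkm, the muscle-type phosphofructokinase, at -5.85, by the lactate carrier Slc16a3 at -3.09 and by hexokinase 2, Hk2, at -2.87. Mitochondrial ribosomal proteins differed less, with a median of -0.38 and 4 of 76 genes at least 2-fold lower. The list of mitochondrial biogenesis, dynamics and import had a median of -0.18 at percentile 1.42, and at percentile 4.66 of random lists that were not matched on level. Within it Ppargc1a, a coactivator that drives mitochondrial biogenesis, differed by -2.81 and the fusion protein gene Mfn2 by -2.21. No probe was matched by name to the mitochondrially encoded transcripts, which were not analysed here.

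**Figure D2:**
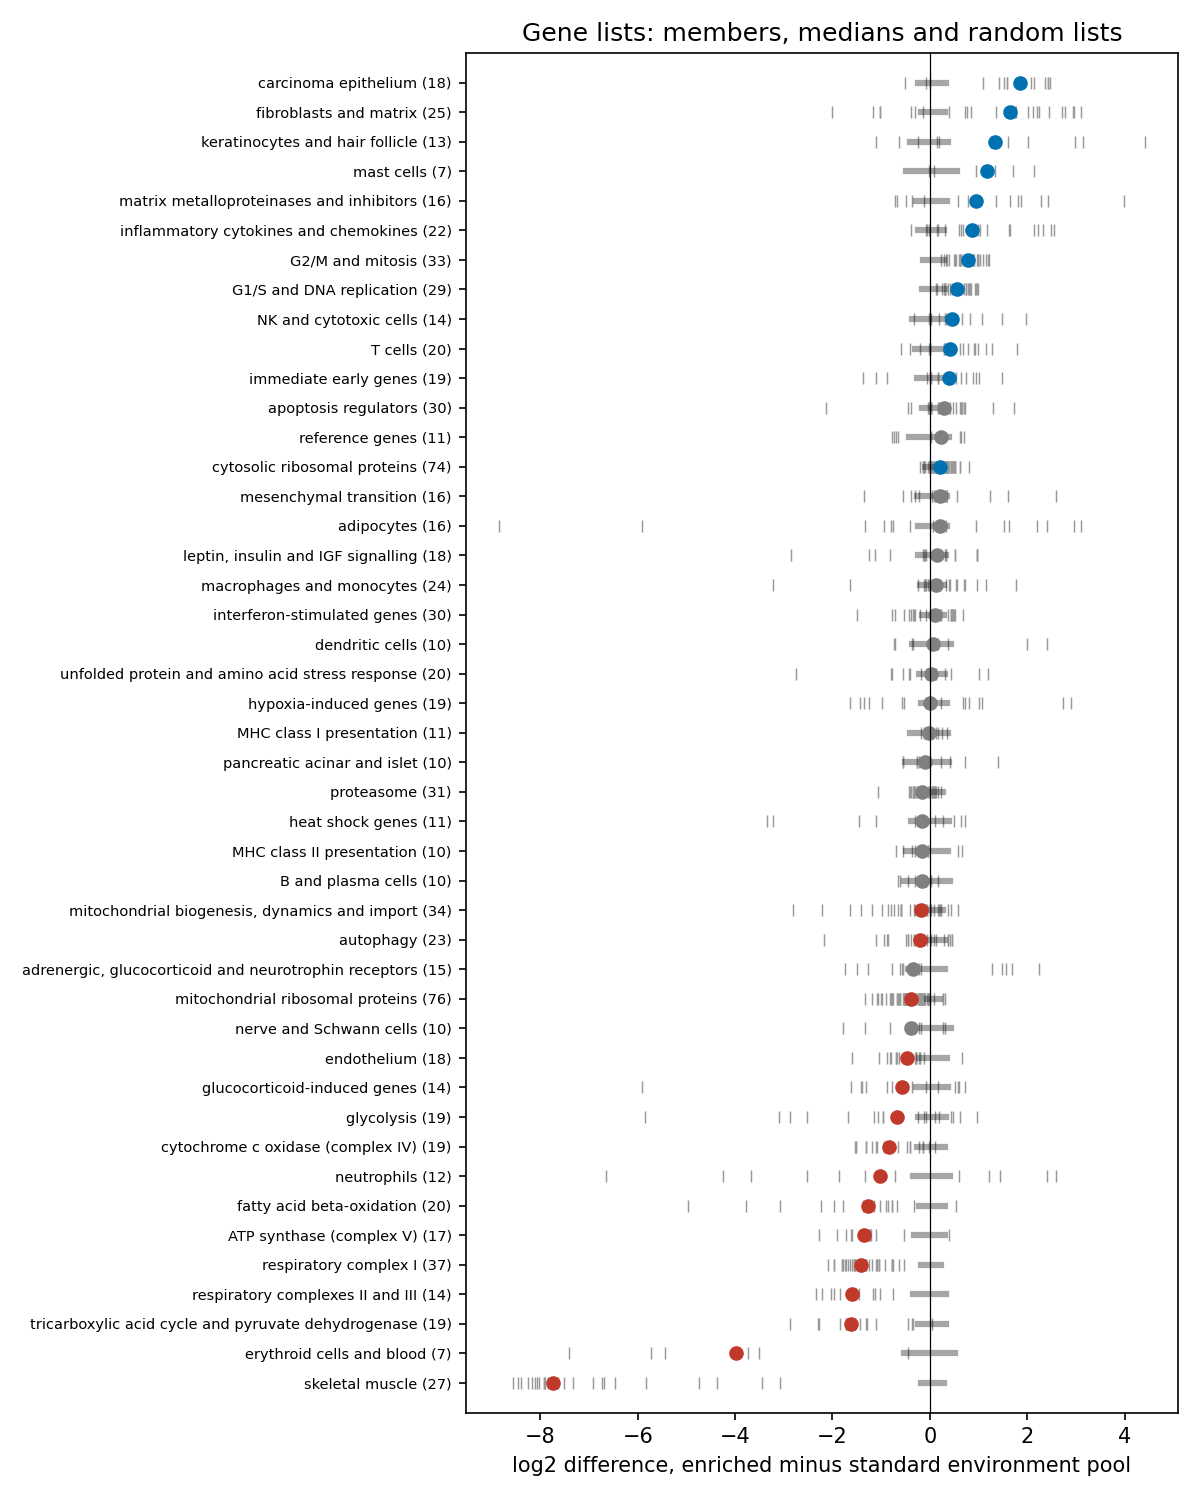
Log2 difference, enriched minus standard environment pool, of the measured members (ticks) and the median (circle) of each gene list with at least 5 measured genes, 1 array per pool; the number of measured genes is in parentheses. Grey bars span the central 95% of the medians of 10000 random lists matched on level, and circles are red for medians below that range, blue for medians above it and grey for the others; skeletal muscle at -7.73 has the lowest median and carcinoma epithelium at 1.85 the highest, and single members lie beyond both.

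Isoforms that serve the same step in different tissues did not move together. Cox6a2, Cox7a1 and Cox8b, the cytochrome c oxidase subunits typical of muscle or brown fat, differed by -8.03, -6.46 and -6.99, whereas their general counterparts Cox6a1, Cox7a2 and Cox8a differed by -0.22, -0.85 and 0.10. The muscle-type nucleotide carrier Slc25a4 differed by -3.83 and Slc25a5 by 0.13, and Cpt1b by -4.97 against 0.55 for Cpt1a. Over the 6 mitochondrial pairs the median was -6.73 for the muscle-type isoforms, of which Cox6a2 and Cox7a1 are also in the muscle list, and 0.12 for the general isoforms. The pairs were named after Ckmt2 and Cox6a2 had been seen among the lowest genes and before the values of the general isoforms were seen. The general median stayed between 0.09 and 0.36 under the alternative processings. Over 5 glycolytic pairs, chosen after their values were seen, the medians were -5.85 for the muscle-type and 0.18 for the general isoforms.

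**Figure D3:**
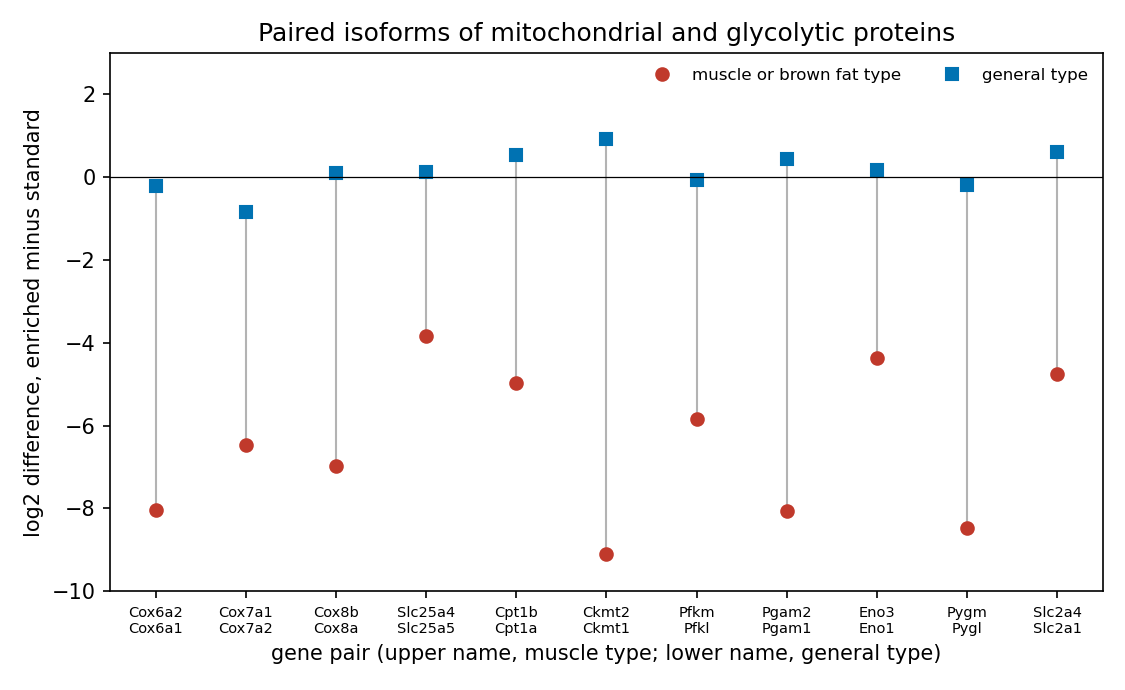
Log2 difference, enriched minus standard environment pool (y axis), of 11 pairs of genes that encode tissue variants of the same protein, 1 array per pool. Circles are the variants typical of muscle or brown fat, which lie between -9.11 (Ckmt2) and -3.83 (Slc25a4), and squares their general counterparts, which lie between -0.85 (Cox7a2) and 0.93 (Ckmt1); the 5 glycolytic pairs at the right were chosen after their values were seen.

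Genes of ductal epithelium and tumour stroma were higher in the enriched environment pool, in which the muscle list was lower. In the carcinoma epithelium list 15 of 18 genes were at least 2-fold higher, at percentile 100 of the random lists. Tff2, a secreted trefoil peptide, differed by 2.48, the membrane mucin Muc4 by 2.44 over 5 probes (SD between probes 0.12), the surface antigen Msln by 2.43, the epithelial cadherin Cdh1 by 2.37, the keratin Krt8 by 2.14 and the adhesion molecule Epcam by 2.07. The list took 0.337% of the summed signal in the standard and 1.23% in the enriched environment pool. The fibroblast and matrix list was higher at its median but not uniform. Col12a1 at 3.11, Col3a1 at 2.96 and Postn at 2.95 led 14 genes that were at least 2-fold higher, while 4 genes were at least 2-fold lower, namely Ogn, with levels of 4.16 and 2.16, Pdgfrb at -1.17, Dcn at -1.03 and Pdgfra at -1.02. Matrix metalloproteinases and their regulators had a median of 0.95, with Mmp3, a stromelysin, at 3.98 and Mmp10 at 2.43. The Mmp10 level in the standard environment pool, -5.17, lay near the lowest signal well above background there, -5.685. The keratinocyte and hair follicle list had a median of 1.33, led by the basal and stress keratins Krt17 at 4.42 and Krt14 at 3.15, and without a filter on dim probes this median was 0.16 and no longer outside its random lists. The Krt8 probes lie on chromosome 15, from 101982940 to 101982999 and from 101983072 to 101983131 on mm7.

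Proliferation genes were slightly and evenly higher in the enriched environment pool, in which the muscle list was lower by -7.73. All 29 measured genes of the G1/S and DNA replication list were higher, with a median of 0.56 and none past 2-fold, Mcm3 at 0.99 being the furthest. All 33 genes of the G2/M and mitosis list were higher, with a median of 0.77, and 5 were at least 2-fold higher, Nek2 at 1.21, Kif23 at 1.19, Foxm1 at 1.16, Ndc80 at 1.09 and Cdc25b at 1.04. Outside the proliferation lists, cytosolic ribosomal proteins had a median of 0.21 and immediate early genes a median of 0.40, both above their random lists. The 19 immediate early genes split, with 15 higher and 4 lower. Fos at 1.49 and Junb at 1.01 were at least 2-fold higher, and Fosb at -1.37 and Nr4a1 at -1.11 at least 2-fold lower.

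Immune transcripts differed by class, beside the same difference of -7.73 in the muscle list and of -3.98 in the erythroid list. Inflammatory cytokines and chemokines had a median of 0.87, with the monocyte attractant Ccl8 at 2.55, the cytokine Il6 at 2.33 and the neutrophil attractants Cxcl5 at 2.22 and Cxcl1 at 2.13. In the standard environment pool the levels of Il6, -4.81, and Cxcl1, -5.05, lay near the lowest signal well above background there, -5.685. T cell genes had a median of 0.42, from 0.22 to 0.81 over the alternatives. Of 20 measured T cell genes 15 were higher, 3 of them at least 2-fold with Thy1 at 1.80 and Icos at 1.28, and 5 were lower, among them the coreceptor gene Cd4 at -0.59 and Cd28 at -0.42. Natural killer and cytotoxic genes had a median of 0.45 (0.22 to 0.52 over the alternatives), with Eomes at 1.97, and mast cell genes one of 1.18 (0.73 to 1.52), with the chymase Cma1 at 2.14. The T cell and natural killer medians were smaller than the G1/S median of 0.56, and whether these cells were more numerous was not tested. The cytokine, T cell, natural killer and mast cell lists lay above their random lists. The neutrophil list lay below, at -1.02 (from -2.20 to -0.90 over the alternatives), but its members split. Mpo, the myeloperoxidase gene of immature granulocytes, differed by -6.65, Mmp8 by -4.25 and Retnlg by -3.67, while Clec4e at 2.59 and Clec4d at 2.40 were higher. Among macrophage genes, whose list lay within its random lists at 0.12, Arg1 differed by 1.77 and Chil3 by -3.23. Interferon-stimulated genes, at a median of 0.11, B and plasma cell genes, at -0.16, and dendritic cell genes, at 0.06, lay within their random lists, as did both antigen presentation lists, at -0.01 for class I and -0.16 for class II.

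Marker genes of some other tissues differed between the 2 pools. Erythroid and blood genes were lower in 7 of 7 measured members. Slc4a1, the anion exchanger of red cells, differed by -7.40, the alpha globin gene Hba-a1 by -5.72 and Alas2, the first enzyme of erythroid haem synthesis, by -5.45. In the adipocyte list, at 0.20 and within its random lists, the brown fat genes Ucp1 at -8.86 and Cidea at -5.91 were lower, while the adipokine genes Cfd at 3.11, Retn at 2.96 and Adipoq at 2.40 were higher. Endothelial genes had a median of -0.47, with Flt1 at -1.60 and Tie1 at -1.05, and lay below their random lists. Genes of nerve and Schwann cells, at -0.38, and of pancreatic acini and islets, at -0.10, lay within theirs.

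Receptors and targets of stress and growth signals showed large single differences. In the list of adrenergic, glucocorticoid and neurotrophin receptors, whose median of -0.35 lay within its random lists, the neurotrophin receptor Ntrk2 differed by 2.23, the neurotrophin Bdnf by 1.68 and the adrenergic receptor gene Adra1a by -1.75. Genes induced by glucocorticoids had a median of -0.57, below their random lists, with Pdk4, a kinase that blocks pyruvate oxidation, at -5.91, Klf9 at -1.61 and Tsc22d3 at -1.40, in the pool in which the muscle list was lower by -7.73. Leptin, insulin and IGF signalling, at 0.14, hypoxia-induced genes, at 0.00, unfolded protein response genes, at 0.02, heat shock genes, at -0.16, and mesenchymal transition genes, at 0.20, lay within their random lists, although Igfbp5 differed by -2.86, Hspb1 by -3.34 and Twist2 by 2.59. Of the hypoxia genes 4 were at least 2-fold higher, led by Angptl4 at 2.89 and Stc2 at 2.74, and 4 at least 2-fold lower, led by Egln3 at -1.64 and Higd1a at -1.44. Autophagy genes, at -0.20 and percentile 2.32, lay below theirs by a margin that 6 of 12 alternatives removed. Apoptosis regulators, at 0.30 and percentile 97.31, proteasome genes, at -0.16 and percentile 3.36, and the reference genes, at 0.24, lay within.

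The genes that were furthest above their standard environment level in the enriched environment pool did not belong to 1 group. Saa3, an acute-phase apolipoprotein, was at -2.41 in the standard and at 3.25 in the enriched environment pool, a difference of 5.67 or 50.8-fold. Rhox5, a homeobox gene of the germline and placenta, differed by 5.56, the neural adhesion gene Chl1 by 4.77, the neuropeptide gene Calcb by 4.72, Krt17 by 4.42, the germ cell gene Tex101 by 4.41, the complement regulator Cfi by 4.38 and Cpxm1 by 4.37. Nnat, Il5ra, Mmp3, Lrrc15, S100g, Prss35 and C1qtnf3 followed, between 3.99 and 3.74. Cfi, Nnat, Il5ra and Prss35 were at -4.97, -4.75, -5.17 and -4.98 in the standard environment pool, near the lowest signal well above background there, -5.685. The Saa3 probe lies on chromosome 7 from 42888862 to 42888921 on mm7. Among genes well above background on 1 array only, the largest bounds were in Eraf, Abra, Eef1a2, Vgll2 and Camp on the standard environment array, at least 707-fold, 406-fold, 395-fold, 335-fold and 290-fold brighter there. On the enriched environment array they were in the secreted lectins Reg1 and Reg3g and in Sucnr1, Gzmc and Wnt2, at least 43.1-fold, 21.3-fold, 19.2-fold, 14.96-fold and 14.8-fold brighter there.

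Of the 46 lists, 45 could be ranked, 15 lay below and 12 above their random lists. Within an array, repeated spots of a probe had a median SD of 0.05 in the standard and 0.06 in the enriched environment pool, and different probes of a gene had a median SD of 0.17 in their differences, which cover technical error only and not the spread between mice. The number of genes at least 2-fold higher was 669 with normexp and 714 with no background correction, the number at least 2-fold lower was 3796 without a filter on dim probes, and 11 of the 18 lists within their random range changed sign under at least 1 alternative.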

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

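All alternatives named here were chosen before the data were examined. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Of the 27 lists that stood apart, 22 kept that call under all 12 alternatives, and 2 of the other 5, natural killer and mast cells, lost it because too few genes were left above the median level. No list that stood apart changed sign under these 12, and no gene named by the fixed rule with at least a 2-fold difference did under the 11 that give values per gene, wherever it was measured. Of the 18 lists within their random range, 11 changed sign under at least 1 alternative. The 1190 genes at least 2-fold higher became 669 with normexp, 714 without background correction, 593 above the median level, 3131 at 1.5-fold and 467 at 3-fold. The 1972 genes at least 2-fold lower became 3796 without a filter, 967 above the median level, 3786 at 1.5-fold and 978 at 3-fold. Filters and thresholds change these counts by construction, and the cause of the others was not tested. The 2 counts became 1415 and 1715 under quantile normalization and 1492 and 1763 in the authors' table. Under quantile normalization 1184 of the 1190 and 1712 of the 1972 genes stayed past the threshold. Quantile normalization moved the list medians of ATP synthase to -1.12 and of cytosolic ribosomal proteins to 0.44, and the authors' table moved them to -1.09 and 0.46, complex I to -1.25, the proteasome to 0.086 and MHC class I to 0.23. Autophagy came within its random range with quantile normalization (-0.12), loess (-0.23), normexp (-0.16), no background correction (-0.19), the authors' table (-0.10) and unmatched random lists (-0.20), as did mitochondrial biogenesis with unmatched lists (-0.18) and keratinocytes with no filter (0.16). Apoptosis regulators left it with quantile normalization (0.33), loess (0.21), probes above background on at least 1 array (0.30), the brightest probe (0.33) and unmatched lists (0.30). So did the proteasome with the brightest probe (-0.20), adipocytes with probes above background on at least 1 array (0.34) and the adrenergic, glucocorticoid and neurotrophin receptors with normexp (-0.39). The erythroid median ranged from -5.45 to -3.63 and that of glycolysis from -0.98 to -0.46. Pancreatic genes moved to -0.56 above the median level, and the cause of these changes in the lists was not tested. Signal over background limits the dim genes, since 5989 genes were well above background on neither array.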

Other observations

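Of the tests below, those of dilution for the carcinoma, matrix and cell cycle lists were chosen after the result was seen, as were the brown adipocyte and bone lists and the genes of the next paragraph.

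Some genes outside the fixed lists were higher in the enriched environment pool. Vil1, which encodes the microvillus protein villin, differed by 3.66, Cdh17, a cadherin of intestinal epithelium, by 2.59, the intestinal transcription factor gene Cdx2 by 2.59 and the stem cell receptor gene Lgr5 by 2.51. Hp, which encodes haptoglobin, was at 4.63 in the standard and at 7.32 in the enriched environment pool, Saa2 differed by 2.70, Serpina3n by 3.69 and Lrg1 by 2.29. The germ cell genes Ssx9, Tdrd12 and Ssxb1 differed by 2.72, 2.64 and 2.54. Lep, the gene of leptin and a member of the adipocyte list, was well above background in the enriched environment pool only, at least 9.52-fold brighter there.

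Genes of other tissues were lower in the enriched environment pool beside those of muscle. All 7 measured genes of the brown adipocyte list were at least 2-fold lower in the enriched environment pool, with a median of -4.47, and 4 of its 10 members are also in a fixed list. In the bone list 5 of 5 measured genes were lower, with a median of -0.83 that ranged from -3.53 to -0.63 over the alternatives. Only 2 of the 5 were at least 2-fold lower, Bglap, the gene of osteocalcin, at -6.82 and Alpl at -4.02. Ibsp was at least 14.98-fold brighter in the standard environment pool. The muscle transcripts Tnni2, Tcap and Acta1 were at 9.02, 8.53 and 8.17 in the standard environment pool, against 5.94, 0.79 and 0.84 in the enriched environment pool. The muscle genes also included Myf6 at -6.88 and Chrna1, a subunit of the acetylcholine receptor of the muscle endplate, at -4.33.

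The first pattern is the lower level of respiratory chain, tricarboxylic acid cycle and beta-oxidation genes in the enriched environment pool. Scaling and background correction are argued against as its cause, since the highest median of these lists over all scalings and backgrounds was -0.61. A fall of all mitochondrial transcripts alike in the tumour cells is argued against only as far as the general isoforms did not share it. Their median lay 1.46 above that of the 84 shared subunits, at -1.35. The 2 sets are unlike, so the test cannot decide for the shared subunits. A smaller fall of the general isoforms cannot be told apart either. The G1/S list was higher by a median of 0.56, so a difference of 0 may not mark an unchanged level. Of the general isoforms only Cox6a1 at -0.22, Cox7a2 at -0.85 and Cox8a at 0.10 are chain subunits. All belong to complex IV, whose list median was -0.85. Skeletal muscle or brown fat RNA in the standard environment pool is a candidate explanation, because it predicted that the general isoforms would stay near 0, and their median was 0.12 while that of the muscle-type isoforms was -6.73. A fall of part of these transcripts in the tumour cells and an effect of the housing remain open. Whether muscle entered through invasion, dissection or 1 of the pooled tumours was not tested.

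The second pattern is the higher level of carcinoma, matrix and cell cycle genes. An even dilution of all tumour RNA by muscle RNA in the standard environment pool is argued against for the carcinoma list, whose lower quartile lay 0.64 above the upper quartile of the G1/S list. This holds only on the condition that the RNA added to that pool carried few G1/S transcripts of its own, which was not tested. Bone marrow RNA, a candidate below, may carry them. For the matrix list the quartiles could not decide, because its lower quartile minus the upper quartile of the G1/S list was -0.96, with 7 of 25 genes lower. The genes at least 2-fold higher were 14 of 25 against 0 of 29 in the G1/S list. At 1.5-fold they were 17 and 12, and at 3-fold 13 and 0. The lower bootstrap limit of the difference was 36.0, 0.81 and 32.0 percentage points, and it stayed above 0 under every alternative. The draws took genes as independent and hold no spread between mice or arrays. At 2-fold and 3-fold no G1/S gene passed, so the draws gave the share of that list no spread. On the same condition, these shares argue against an even dilution as the whole cause for the matrix list in these 2 pools. They do not separate a shift of the matrix list from its wider spread. An even dilution cannot be told apart from a change in the tumour for the cell cycle lists. Their lower median minus the higher of the T cell and macrophage upper quartiles was -0.35. Skin in the enriched environment pool is argued against as the main source of the carcinoma list only on a condition that was not tested. Signals from probes of different genes would have to compare as amounts of RNA. The keratinocyte list took 0.059% of the summed signal there, against 1.23% for the carcinoma list, a comparison chosen after the result was seen. A smaller part from skin cannot be told apart. The 4 measured genes of differentiated epidermis had a median of -0.051, within their spread of the bound of 0 set beforehand (-0.71 to 0.55 over the alternatives). Lor and Krtdap lay near the lowest measurable signal, and Krt14 at 3.15 and Krt5 at 2.01 go with skin. A larger share of carcinoma cells and stroma, or an effect of the housing, may remain and was not tested.

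The third pattern is the lower level of erythroid genes. Bone marrow RNA in the standard environment pool is a candidate explanation, because it predicted lower levels of the granule protein genes of neutrophil precursors, and the 4 measured ones had a median of -3.59, from Mpo at -6.65 to Prtn3 at -0.65 (median from -6.53 to -3.05 over the alternatives). Camp, Ngp and Elane were at least 290-fold, 234-fold and 20.8-fold brighter in the standard environment pool. The median of the neutrophil list had been seen before this test, and 5 of the 7 granule genes are members of that list. Blood cell formation within the tumours, or an effect of the housing on it, remains open and was not tested.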
